A study of Mus musculus with 5 samples.

How the data were processed

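RNA from the rostral part of the medial ganglionic eminence (MGE), the ventral forebrain region where many cortical interneurons are born, was measured on 5 Affymetrix mouse expression arrays. Per the labels, the dissected ventricular and subventricular zones came from embryos at embryonic day 15.5, wild type (WT) or mutant for the homeodomain transcription factors Dlx1 and Dlx2. There was 1 WT and 2 mutant arrays of tissue, and 1 WT and 1 mutant array of primary neuronal cultures prepared from the same zones. The labels do not say whether the 2 mutant tissue arrays came from separate embryos or pools, so p-values rest on the spread between these arrays, which may be technical. Across both preparations they rest also on the disagreement between tissue and culture. The 2 mutant tissue arrays were not copies of each other: the difference between them had an SD of 0.324 (log2) over the genes tested.

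The authors deposited linear intensity values, 1 per probe set, for 45101 probe sets. The values themselves show that each array was scaled so that the mean left after trimming 2% of probe sets at each end was close to 150 (149.94 or 149.95 in every array). The software that made them is not given in the sources used here, and no detection calls were used here. Array medians ranged from 26.2 (culture WT) to 29.8 (tissue WT) in signal, a range of 0.183 on the log2 scale. This passed the limit of 0.1 set in advance for keeping the deposited scaling, so the arrays were quantile normalized, and the deposited scaling became an alternative. Values below the pooled 20th percentile (a signal of 5.15) were set to it, and log2 was taken. A direct difference from a group wholly at this floor is a lower bound, while a fitted one is not read as a bound.

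Probe sets were named through the platform annotation supplied with the series. Of the 45101 probe sets, 34958 had 1 gene symbol, 932 had several and 9211 had none here. The 64 control probe sets were left out of every test. Of the probe sets with 1 symbol, 34754 matched a RefSeq gene table by Entrez identifier and 0 needed an update. No probe set with several symbols was used. The probe set with the highest mean log2 signal over the 5 arrays stood for each of 18193 genes. Genes whose mean lay above the pooled median of all values (4.80 log2, a signal of 27.8) were tested, 11063 in all. No genome build was used, so no coordinates are given. Other probe sets of a gene can differ from the brightest one in size or sign, and the text gives some such cases, not all.

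All tests used limma 3.58.1 in R 4.3.3 with an intensity trend in the prior variance, and Benjamini-Hochberg adjusted p-values below 0.05 counted as past the threshold. The genotype effect in tissue used the 3 tissue arrays (1 residual degree of freedom, to which the prior added 10.89). The effect across both preparations was the genotype term of a model with preparation and genotype over 5 arrays (2 residual and 5.95 prior degrees of freedom), whose spread includes any disagreement between tissue and culture. The preparation effect, culture minus tissue, came from the same model. The interaction, the culture genotype effect minus the tissue genotype effect, came from a model of the 4 groups (1 residual and 8.57 prior degrees of freedom). In the tissue model and the model of the 4 groups, single arrays were assumed to vary like the pair of mutant tissue arrays. The culture arrays, 1 against 1, received no test: genes that differed by at least 2-fold were counted. The number of arrays limits the precision of every value.

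For gene lists, 24 lists of 464 genes were fixed before the data were examined, 431 of them with a named probe set and 345 tested. They covered the targeted genes, GABA synthesis and transport, MGE and interneuron transcription factors, interneuron peptides, striatal genes, progenitor and Notch genes, the oligodendrocyte lineage, pallial genes, and septal, preoptic and diencephalic genes. Others covered the cytoskeleton and neurite growth, migration and guidance, synapse and excitability, cell cycle, immediate early genes, cholesterol synthesis, glycolysis and hypoxia, and stress. Markers of astrocytes, microglia, endothelium, pericytes, red blood cells and choroid plexus, and sex-linked genes, completed the set. Lists were tested with camera (preset correlation between genes of 0.01), Benjamini-Hochberg adjusted over the 24 lists. Camera with an estimated correlation and fry were alternatives. With an estimated correlation, camera rests on the residual degrees of freedom, 2 or 1 here, so a list could hardly pass. For the oligodendrocyte list across both preparations the estimated correlation was −0.0863, yet the unadjusted camera p went from 1.8e-08 to 0.028. A loss of calls under it therefore cannot by itself tell whether correlation between genes made them. Among lists called across both preparations, the estimated correlation reached 0.96 for cell cycle genes and 0.94 for the targeted genes. It was 0.21 for the cytoskeleton, red blood cell, and septal, preoptic and diencephalic lists. For these lists the preset of 0.01 may overstate the evidence. The camera tests of the tissue effect and of the interaction were added after the data had been seen. In culture, a list's median was placed among the medians of 10000 random lists matched on mean expression in 20 bins, as a description of those arrays.

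The genes named in the text follow a rule written before the data were examined. It took Dlx1 and Dlx2, 16 genes always named, and the largest changes past the threshold each way: 10 across both preparations, 8 in tissue, 8 in culture without a test, 12 between preparations and 5 for the interaction. Those across both preparations had to lie on the same side of WT in every mutant array. Those in tissue had to differ at least 2-fold in both mutant arrays. Those between preparations needed the same sign in both genotypes. It added up to 4 members of each list. Of the 16 genes always named, 2 had no named probe set and were not analysed here. Clone and predicted names were left out.

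Each model was tested on simulated data with 11063 genes, 200 of them changed, in 10 simulations per model. For every model the spread came from the fit across both preparations, and noise was drawn independently for each gene and array. With the spread drawn as observed, the tissue model recovered 67.9% of changes of 1 and 89.1% of changes of 2 (log2), and 20.6% of its calls were false. The model across both preparations recovered 77.9% and 94.5% with 9.78% false calls, and the preparation term 76.6% and 96.3% with 7.38% false. The interaction recovered 32.3% and 81% with 20% false. False calls thus exceeded the share that a threshold of 0.05 aims at in each model, most in those with 1 residual degree of freedom. With the spread drawn from the fitted prior instead, recovery of changes of 1 was 36.2% in tissue, 56.9% across both preparations, 53.1% for preparation and 5.1% for the interaction, and false calls made up 13.1%, 6.25%, 4.9% and 9.34% of calls. A list of 30 genes shifted by 0.5 was called in 10 of 10 simulations of the model across both preparations with either spread, and an unshifted list in 0 and 1. Because the simulated genes varied independently, these rates may not hold for lists of co-regulated genes. Nor do they cover an unusual single array.

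Alternatives were the deposited scaling, no floor (log2 of the value plus 1), a floor at the 40th percentile, no filter or a stricter filter (70th percentile) on dim genes, the mean of a gene's probe sets, every probe set tested on its own, and no intensity trend. Leaving out either mutant tissue array, the spread of the model over both preparations for the tissue effect, and a test of the culture arrays in the model of the 4 groups were also run. Alternatives added after the data had been seen left out sex-linked genes, used mutant arrays alone for the preparation effect, or left out genes with equal values in both mutant tissue arrays. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.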

Results

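Expression profiles from 5 arrays were used here to ask which genes differ with loss of Dlx1 and Dlx2 in MGE tissue and cultures. Particular attention went to genes of neurite growth and migration. The 5 arrays fell into 4 groups: MGE tissue from WT embryos (1 array), MGE tissue from Dlx1/2 mutants (2 arrays), primary MGE cultures from WT embryos (1 array) and primary MGE cultures from mutants (1 array), all from E15.5 embryos. Each array held 45101 probe sets, and 11063 genes were bright enough to test. Only mutant tissue was replicated, so levels in the other 3 groups carry no replicate error of their own. Differences are given on the log2 scale as mutant minus WT, or culture minus tissue, with the standard error (SE) of the limma fit where a test was made.

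The targeted genes followed the labels in every array. The 1 named probe set of Dlx1 had a deposited signal of 3278 in WT tissue against 2.80 and 0.921 in the mutant tissue arrays, and of 603 in WT culture against 1.26 in mutant culture. Its mutant values all lay at the floor, so the fall was at least 620-fold in tissue and at least 117-fold in culture (adjusted p = 0.00044 across both preparations). The 1 named probe set of Dlx2 read 1069 in WT tissue, 18.7 and 11.7 in mutant tissue, 331 in WT culture and 21.7 in mutant culture (log2 −5.21 ± 0.47 across both, adjusted p = 0.0029). As a list the 2 targeted genes passed, also adjusted over the list alone (median −6.73, camera adjusted p = 8.5e-07, and 0.32 with an estimated correlation). Since the mutants are defined by these genes, the call restates the genotype. Where these probe sets lie relative to the deleted sequence was not analysed here. The non-coding RNA Dlx1as, transcribed from the strand opposite Dlx1, fell from 1269 to 1.88 and 1.58 in tissue and from 673 to 2.31 in culture, with all mutant arrays at the floor (adjusted p = 0.00016 across both). The linked pair Dlx5 and Dlx6, known targets of Dlx1 and Dlx2, were also low in mutants. Dlx5 fell by 3.65 ± 0.24 (12.6-fold, adjusted p = 0.00069) and the non-coding Dlx6os1 by 5.98 ± 0.28 (adjusted p = 0.00016, with mutant culture at the floor). Dlx6 was too dim on average to be tested. Its signal was 172 in WT tissue, 4.14 and 6.56 in mutant tissue, 26.0 in WT culture and 2.77 in mutant culture.

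Across both preparations, the strongest fall in mutants after the Dlx genes was in Slc32a1, the vesicular transporter that loads GABA into synaptic vesicles, by 4.60 ± 0.25 (24.2-fold, adjusted p = 0.00026). Maf, a transcription factor of MGE-derived interneurons, fell by 2.74 ± 0.14 (adjusted p = 0.00025), and Lhx8, a LIM-homeodomain factor of basal forebrain cholinergic neurons, by 2.69 ± 0.28 (adjusted p = 0.0049). The potassium channel subunit Kcns2 fell by 2.46 ± 0.25 (adjusted p = 0.0049). The largest rises were in Otp, a homeodomain factor of hypothalamic neuroendocrine neurons (3.35 ± 0.48, adjusted p = 0.023), and Fli1, an ETS factor known from blood and endothelial cells (2.99 ± 0.25, adjusted p = 0.0020). Of 8 endothelial markers 0 passed, with a median of −0.14 that joins −0.35 in tissue and 0.39 in culture, where 6 lay above 0. Gsx1, a homeodomain factor of ventral telencephalic progenitors, rose by 2.39 ± 0.20 (5.25-fold, adjusted p = 0.0020). Other large rises were Far2, a fatty acyl-CoA reductase (2.55), the ubiquitin ligase Marchf1 (2.55), the transcription factor Ebf3 (2.23), Nt5dc3 (2.06), the A-type potassium channel gene Kcnd2 (2.01), Chodl (1.97) and Igsf21 (1.78). All of these genes lay on the same side of WT in 3 of 3 mutant arrays. The naming rule required this, so it is not separate evidence.

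In all, 90 genes were higher and 28 lower in mutants across both preparations, of which 42 and 22 differed by at least 2-fold, and 1443 genes had an unadjusted p under 0.05. Left with either one of the mutant tissue arrays, the model called 18 genes higher and 17 or 18 lower, of which 34 or 35 were among the 118. The calls of Otp, Marchf1, Nt5dc3 and Chodl were lost both ways, and that of Far2 was lost without replicate 2. Far2 without replicate 1, and Ebf3 (adjusted p = 0.044) in both runs, were not among the genes tested. Kept both ways were those of the Dlx genes, Slc32a1, Maf, Lhx8, Kcns2, Fli1, Gsx1, Kcnd2 and Igsf21. Without an intensity trend in the variance prior 1 gene was higher and 3 lower, averaging a gene's probe sets left 24 and 11, and testing dim genes too left 0 and 0.

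**Figure D1:**
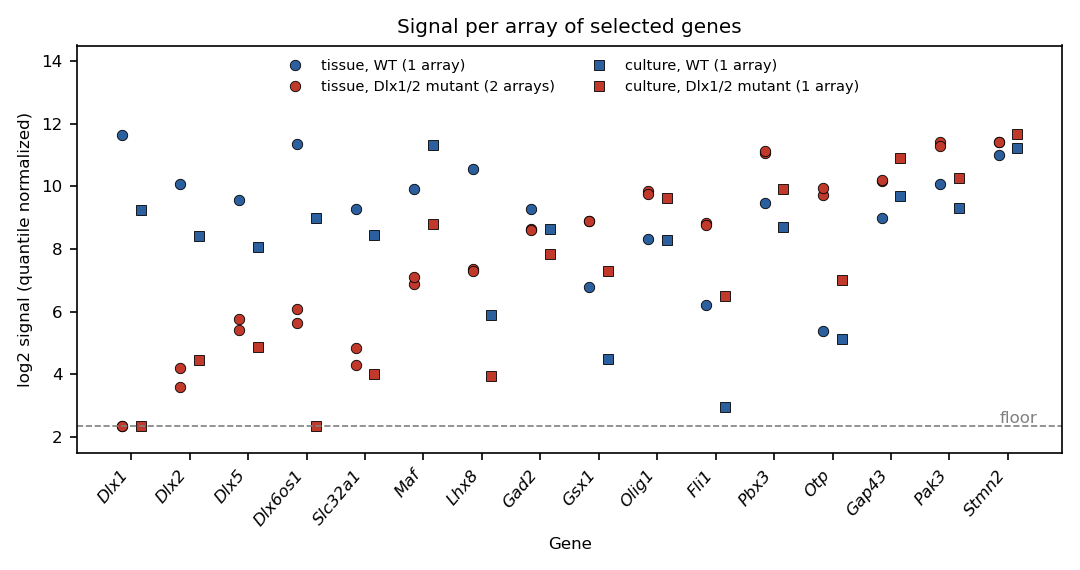
Normalized log2 signal (vertical axis) of 16 genes (horizontal axis) on each of the 5 arrays, as circles for tissue and squares for culture, blue for WT and red for mutant; the dashed line is the floor at 2.36. The Dlx genes, Slc32a1, Maf, Lhx8 and Gad2 were lower and Gsx1, Olig1, Fli1, Pbx3, Otp, Gap43, Pak3 and Stmn2 higher in every mutant array than in the WT array of the same preparation.

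Genes of GABA synthesis and transport were lower in mutants as a list (median −0.30 over 6 genes, camera adjusted p = 0.00081; adjusted p = 0.33 with an estimated correlation). Slc32a1 and Gad2, one of the GABA-synthesizing enzymes, fell (Gad2 by 0.70 ± 0.12, adjusted p = 0.046), 4 members did not pass, and 3 fell when adjusted over the list alone. The Gad2 call was lost when either mutant tissue array was left out. Gad1, the other such enzyme, differed by −0.46 (adjusted p = 0.23). Of 11 MGE and interneuron transcription factors tested, 4 fell and 0 rose: Dlx5, Maf, Lhx8 and Zeb2, a zinc finger factor of interneuron migration (Zeb2 −1.56 ± 0.22, adjusted p = 0.022, lost without mutant tissue replicate 1). The list's median was −0.16 (camera adjusted p = 0.0036; adjusted p = 0.33 with an estimated correlation), and adjusted over the list alone 2 were higher and 5 lower. That median joins 0.07 in tissue and −0.67 in culture. Lhx6, a factor that specifies MGE interneurons, differed by −0.84 ± 0.16 and missed the threshold (adjusted p = 0.054, and 0.0499 with the deposited scaling kept), while Nkx2-1, which specifies the MGE itself, differed by 0.21 ± 0.40 (adjusted p = 0.86). Of 8 interneuron peptides and markers, 1 passed: Npy, the gene of neuropeptide Y, rose by 1.03 ± 0.17 (adjusted p = 0.036, lost when either mutant tissue array was left out; list camera adjusted p = 0.56; 3 higher and 2 lower adjusted over the list alone). Of 14 striatal genes, Pbx3 rose by 1.45 ± 0.12 (adjusted p = 0.0018) and Ebf1 fell 2.83-fold (adjusted p = 0.016, lost when either mutant tissue array was left out), and the list did not shift as a whole (camera adjusted p = 0.82).

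The progenitor and Notch list was higher in mutants (median 0.34 over 29 genes, camera adjusted p = 2.0e-08; adjusted p = 0.32 with an estimated correlation). In it 3 genes rose over all genes tested and 15, with 1 lower, adjusted over the list alone. The 3 were Gsx1, the HLH inhibitor Id4 (0.95 ± 0.08, adjusted p = 0.0018) and the Notch ligand Jag1 (0.81 ± 0.13, adjusted p = 0.037, lost when either mutant tissue array was left out). The oligodendrocyte list had a median of 0.73 over 10 genes (camera adjusted p = 1.4e-07; adjusted p = 0.32 with an estimated correlation; fry adjusted p = 0.016). Its 2 members past the threshold, 5 adjusted over the list alone, were Olig1, a bHLH factor of that lineage (1.42 ± 0.11, adjusted p = 0.0018), and the receptor phosphatase gene Ptprz1 (0.70 ± 0.10, adjusted p = 0.022, lost when either mutant tissue array was left out). Olig2 differed by 0.76 ± 0.20 (adjusted p = 0.16). The astrocyte list had a median of 0.46 over 12 genes (camera adjusted p = 5.9e-06; adjusted p = 0.32 with an estimated correlation), with 3 past the threshold and 6 adjusted over the list alone. They were the apolipoprotein gene Apoe (1.22 ± 0.12, adjusted p = 0.0038), the glycolytic gene Aldoc (0.78 ± 0.14, adjusted p = 0.046) and the glutamine synthetase gene Glul (0.66 ± 0.09, adjusted p = 0.014), the last 2 lost when either mutant tissue array was left out.

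The cytoskeleton and neurite growth list was higher in mutants by a small median of 0.11 over 43 genes (camera adjusted p = 1.3e-06, and 0.42 with an estimated correlation). With fry the list did not pass (adjusted p = 0.22). Its median joins 0.27 in tissue and 0.08 in culture, where 26 of 43 lay above 0. In this list 4 genes rose and 0 fell, and 12 rose and 1 fell adjusted over the list alone. Gap43, a growth cone protein, rose by 1.20 ± 0.09 (2.30-fold, adjusted p = 0.0018), with the same difference of 1.20 in tissue and in culture. Pak3, a p21-activated kinase that acts on actin, rose by 1.13 ± 0.11 (2.19-fold, adjusted p = 0.0038), and its 4 probe sets all differed upwards. Basp1 rose by 0.47 and Stmn2 by 0.44, with adjusted p of 0.046 and 0.041, and both calls were lost when either mutant tissue array was left out and with the deposited scaling kept. The microtubule-associated protein genes Map2 and Mapt differed by 0.37 (adjusted p = 0.21) and 0.99 (adjusted p = 0.16), and the actin-binding protein gene Marcks by 0.25 (adjusted p = 0.099). Because Pak3, Gap43, Map2, Mapt and Marcks were put on this list from knowledge of the study, the list is not independent evidence of its direction. Among 41 migration and guidance genes, 2 rose and 2 fell (median 0.19, camera adjusted p = 0.0050; adjusted p = 0.32 with an estimated correlation; fry adjusted p = 0.035; 16 higher and 4 lower adjusted over the list alone). Ackr3, a receptor for the chemokine Cxcl12, fell by 2.01 ± 0.26 (4.02-fold, adjusted p = 0.014) and the ephrin receptor gene Epha5 by 1.20 ± 0.20 (adjusted p = 0.041), although 1 of its 4 probe sets above the intensity filter differed by 0.10. The guidance receptor gene Robo1 rose by 0.90 ± 0.13 (adjusted p = 0.025) and the ephrin gene Efnb3 by 0.84 ± 0.15 (adjusted p = 0.046); of these 4 calls, that of Ackr3 was kept with either mutant tissue array left out. Cxcr4, the other Cxcl12 receptor gene, differed by −0.66 (adjusted p = 0.22). Of 33 synapse and excitability genes, Kcnd2 rose and Nrxn3, a presynaptic adhesion gene, fell by 2.11 ± 0.20 (adjusted p = 0.0038), with no shift of the list past the threshold (camera adjusted p = 0.088; 3 higher and 1 lower adjusted over the list alone).

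The remaining lists past the threshold across both preparations had few or no members that passed on their own. The cell cycle list had a median of −0.39 over 37 genes (camera adjusted p = 1.1e-09; adjusted p = 0.56 with an estimated correlation), with 0 genes past the threshold either way and none adjusted over the list alone. That median joins opposite shifts, −0.84 in tissue and 0.16 in culture, where 35 of 37 lay above 0. The estimated correlation of the cell cycle list was 0.96 and its fry adjusted p 0.56. The call with the preset correlation is therefore no firm evidence of a shift across both preparations. Otp was the 1 member to pass among 6 septal, preoptic and diencephalic genes (median 0.96, camera adjusted p = 0.0050, and 0.38 with an estimated correlation). Adjusted over the list alone, 2 passed. The list's median joins 1.79 in tissue and 0.20 in culture, where 3 of 6 lay above 0. Of 3 pallial genes tested, 0 passed (median 0.94, camera adjusted p = 0.020; adjusted p = 0.33 with an estimated correlation; fry adjusted p = 0.0017), and adjusted over the list alone 2 were higher. Among them the bHLH genes Neurod2 and Neurod1 differed by 1.78 (adjusted p = 0.11) and 0.94 (adjusted p = 0.26). None of 14 cholesterol synthesis genes passed, and 1 fell adjusted over the list alone (median −0.15, camera adjusted p = 0.030; adjusted p = 0.33 with an estimated correlation). None of 6 red blood cell genes passed either way (median −0.30, camera adjusted p = 0.043, and 0.49 with an estimated correlation). That median joins −0.59 in tissue and 0 in culture. The cholesterol call was lost without mutant tissue replicate 1 (adjusted p = 0.057) and the red blood cell call without either replicate (0.24 and 0.25). The lists of immediate early genes, glycolysis and hypoxia, stress, microglia, endothelium, pericytes and mesenchyme, and choroid plexus held 0 genes past the threshold each. Their camera adjusted p-values were 0.998, 0.84, 0.78, 0.998, 0.78, 0.76 and 0.35, with medians between −0.14 and 0.04. Adjusted over the list alone, 2 stress genes were higher and 1 lower, 1 endothelial gene was lower and 1 choroid plexus gene higher. In the lists of immediate early genes, glycolysis and hypoxia, and choroid plexus the median and the direction of the test differed in sign. In all, 13 of 24 lists, the targeted genes among them, passed with the preset correlation, 0 with an estimated one and 3 with fry, which tests each list on its own. Those 3 were the oligodendrocyte, pallial and migration lists. The test with an estimated correlation rests on 2 residual degrees of freedom, so a list could hardly pass it.

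Of 4 sex-linked genes tested, 1 was lower and 1 higher in mutants, and 2 did not pass. Xist, expressed from the inactive X chromosome of females, fell by 2.12 ± 0.21 (4.34-fold, adjusted p = 0.0038), while Kdm5d on the Y chromosome rose by 1.40 ± 0.24 (adjusted p = 0.043, lost when either mutant tissue array was left out) and the Y-linked Eif2s3y differed by 1.55 ± 0.35 (adjusted p = 0.10). The 4 sex-linked genes tested did not pass as a list (camera adjusted p = 0.21), and adjusted over the list alone 3 were higher and 1 lower. With them left out of the test, a choice made after the data were seen, 88 genes were higher and 27 lower. These 115 calls were all among the 118. Leaving genes out does not adjust the others for sex, so this run cannot show whether sex share made any of their calls.

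In tissue alone, 950 genes were higher and 741 lower in the 2 mutant arrays than in the WT array, of which 253 and 141 differed by at least 2-fold, and 3209 had an unadjusted p under 0.05. The largest rises included Npnt, an extracellular matrix protein gene, by 4.48 ± 0.22 (22.3-fold, adjusted p = 1.7e-07), and Otp by 4.46 ± 0.15 (adjusted p = 6.6e-09). They also included the DM-domain factor gene Dmrtb1 by 4.17 ± 0.40, the synaptic adhesion gene Lrfn5 by 3.88 ± 0.36, the sulfotransferase gene Chst12 by 3.34 ± 0.52 and the globin gene Cygb by 3.31 ± 0.32. In WT tissue Dmrtb1 (2.38), Chst12 (2.44) and Lrfn5 (2.81) lay close to the floor of 2.36, so the sizes of these rises are uncertain. Lhx9, a LIM-homeodomain factor, rose from the floor to 7.01 and 6.78 by its brightest probe set, a rise of at least 23.1-fold, but another of its probe sets above the intensity filter differed by −0.20. Nes, the progenitor filament protein gene, rose by 3.38 ± 0.35 by its brightest probe set, while its other probe set above the filter differed by −0.39. After the Dlx genes and Slc32a1 (−4.72 ± 0.30), the strongest falls were in Tiam2, a Rac guanine nucleotide exchange factor gene, by 3.45 ± 0.24 (10.9-fold, adjusted p = 2.8e-06), and Lhx8 by 3.24 ± 0.13 (adjusted p = 3.0e-08). Of the genes always named, Cxcr4 fell by 1.04 ± 0.16 (adjusted p = 0.00097) and Lhx6 by 0.54 ± 0.09 (adjusted p = 0.0021) by its brightest probe set. The other probe set of Lhx6 above the filter differed by 0.30, so its direction in tissue is uncertain. Mapt rose by 1.59 ± 0.10 (3.01-fold, adjusted p = 7.4e-07), Map2 by 0.58 ± 0.07 (adjusted p = 0.00016), Marcks by 0.23 ± 0.06 (adjusted p = 0.021) and Olig2 by 0.37 ± 0.10 (adjusted p = 0.030). Of the other probe sets above the filter, 1 of 3 for Map2 (−0.29) and 2 of 6 for Marcks (−0.47 and −0.03) differed the other way. Gad1 (−0.21, adjusted p = 0.24), Nkx2-1 (0.71, adjusted p = 0.16) and Hes5, a Notch effector gene (−0.12, adjusted p = 0.35), did not pass. The interneuron peptide genes Sst, for somatostatin, and Npy rose by 3.05 ± 0.09 (8.30-fold, adjusted p = 2.6e-09) and 1.40 ± 0.07 (adjusted p = 2.6e-07).

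Cell cycle genes were the group that stood out in tissue: 34 of 37 fell and 0 rose, with a median of −0.84 (camera adjusted p = 3.3e-31; adjusted p = 0.52 with an estimated correlation). The DNA replication licensing inhibitor gene Gmnn fell by 1.18 ± 0.11 and the cyclin gene Ccne2 by 1.22 ± 0.14, while the cyclin gene Ccnd1 fell by 0.36 ± 0.10 (adjusted p = 0.038). Adjusted over the list alone, 35 fell. In the same arrays 21 of 43 cytoskeleton and neurite growth genes rose and 2 fell (median 0.27), 14 of 29 progenitor and Notch genes rose and 1 fell (median 0.27), 7 of 10 oligodendrocyte genes rose (median 0.72) and 9 of 33 synapse genes rose and 2 fell (median 0.42). Adjusted over the list alone, the counts of these 4 lists were 24 and 3, 15 and 2, 8 and 0, and 12 and 2. Their camera adjusted p-values were 1.7e-08, 6.5e-05, 4.4e-06 and 0.00015, with an adjusted p = 0.52 with an estimated correlation for each. Septal, preoptic and diencephalic genes (3 of 6 higher, median 1.79), astrocyte markers (6 of 12 higher, median 0.37) and migration genes (12 of 41 higher, 5 lower, median 0.32) passed with camera adjusted p of 0.00050, 0.0080 and 0.036. Each had an adjusted p of 0.52 to 0.61 with an estimated correlation. Lists that passed across both preparations but not in tissue were GABA genes (1 of 6 higher, 2 lower, median −0.23), MGE and interneuron transcription factors (3 of 11 higher, 5 lower, median 0.07), pallial genes (1 of 3 higher, median 1.03) and cholesterol synthesis (1 of 14 lower, median −0.14). Their camera adjusted p-values in tissue were 0.13, 0.11, 0.17 and 0.17. The camera tests in tissue were added after the data had been seen. Of red blood cell genes 3 of 6 fell (median −0.59, camera adjusted p = 0.0014; adjusted p = 0.52 with an estimated correlation), and endothelial markers had a median of −0.35 with 1 of 8 lower. The poly-A spikes were brighter on the WT tissue array (mean log2 12.1) than on the mutant tissue arrays (11.5 and 11.4), as was the 5′ 18S rRNA control (11086 against 3958 and 728). The tissue counts rest on 1 residual degree of freedom: 0 genes were higher and 2 lower without an intensity trend, 269 and 220 passed with probe sets averaged, and 18 and 12 with the spread of the model over both preparations. With the floor at the 40th percentile 0 genes passed, and 1264 and 1030 passed once 101 genes with equal values in both mutant tissue arrays were left out.

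In culture, where 1 mutant array was set against 1 WT array without a test, 205 genes were at least 2-fold higher and 202 at least 2-fold lower in the mutant. The neuropeptide gene Crh was higher by 4.15, the potassium channel-interacting protein gene Kcnip4 by 3.69, Fli1 by 3.54, the collagen gene Col6a2 by 3.30, the proteoglycan gene Srgn by 2.84, the cathepsin gene Ctsf by 2.83 and Gsx1 by 2.80. Far2 was higher by 3.30. Far2 and Srgn were at the floor in WT culture by their brightest probe sets, so these differences are lower bounds for those probe sets. The other probe set of Far2 above the filter differed by 1.53. WT culture was also close to the floor for Ctsf (2.70), Col6a2 (2.81), Kcnip4 (2.91), Fli1 (2.96) and Crh (3.18). Apart from the Dlx genes, Nxph2, a neurexin ligand gene, differed by −5.29 (39.0-fold), Slc32a1 by −4.44 and the actin-bundling protein gene Pls1 by −3.13, with the mutant at the floor. Reln, the gene of the secreted guidance protein reelin, differed by −2.53. Of the always-named genes, Gad1 differed by −0.79, Gad2 by −0.80, Lhx6 by −1.23, Nkx2-1 by −0.46, Cxcr4 by −0.16, Olig2 by 1.27, Hes5 by 1.64, Pak3 by 0.94, Map2 by 0.10, Mapt by 0.20 and Marcks by 0.27. As lists, the targeted genes (median −5.40), GABA genes (−0.79) and MGE transcription factors (−0.67) lay at percentile 0 of 10000 random lists matched on mean expression, and progenitor and Notch (0.40), oligodendrocyte (0.59), astrocyte (0.53), migration (0.22) and cell cycle genes (0.16) at percentile 100. Near the upper end lay interneuron peptides (0.47, percentile 99.85), cytoskeleton (0.08, 99.8), sex-linked (0.53, 98.9), pallial (0.90, 98.8) and endothelial genes (0.39, 97.1). Near the lower end lay cholesterol synthesis (−0.17, percentile 0.22), glycolysis and hypoxia (−0.14, 1.91), synapse (−0.11, 2.35) and microglia genes (−0.25, 2.43). The other 7 lists lay between percentiles 43.3 and 93.9.

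Tissue and culture differences, which share no array, were compared gene by gene. Of 381 genes that differed at least 2-fold from WT in both mutant tissue arrays, 259 had the same sign in culture (68.0%, 95% binomial interval 63.0 to 72.6), and 73 also differed at least 2-fold the same way. For the 258 higher in tissue the share was 73.6% (67.8 to 78.9) and for the 123 lower 56.1% (46.9 to 65.0). Over all tissue calls, 67.3% of the 950 higher and 47.2% of the 741 lower had the same sign in culture. Over all 11063 genes Pearson's r was 0.25 and Spearman's rho 0.11; genes are not independent replicates, so these values and intervals are descriptions. The interaction term found 245 genes with a more positive genotype difference in culture than in tissue and 251 with a more negative one. Cell cycle genes were the main group: 28 of 37, and 34 adjusted over the list alone, had a more positive difference in culture (median 0.99, camera adjusted p = 2.4e-33; adjusted p = 0.72 with an estimated correlation). Mapt (interaction −1.39 ± 0.13, adjusted p = 0.0011), Map2 (−0.48 ± 0.11, adjusted p = 0.037) and Lhx6 (−0.69 ± 0.15, adjusted p = 0.032) had more negative genotype differences in culture. For Map2, 1 other probe set went from −0.29 in tissue to 0.37 in culture. Genotype differences were also more negative in culture for Sst (interaction −2.51 ± 0.12, adjusted p = 1.3e-05), Npy (−0.86 ± 0.11, adjusted p = 0.0038), Otp (−2.60 ± 0.28, adjusted p = 0.0022) and Reln (−2.54 ± 0.37, adjusted p = 0.0057). Hes5 had a more positive one (1.77 ± 0.15, adjusted p = 0.00068), as did Olig2 (0.90 ± 0.19, adjusted p = 0.028). No interaction call was left without an intensity trend, and 0 and 4 were left with probe sets averaged.

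**Figure D2:**
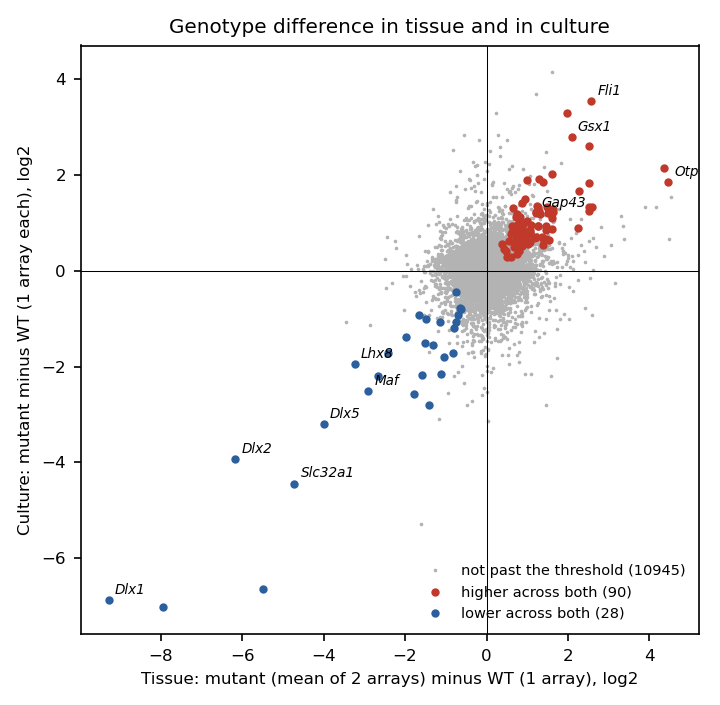
Genotype difference in tissue (mean of 2 mutant arrays minus 1 WT array, horizontal axis, log2) against that in culture (1 array minus 1 array, vertical axis, log2) for 11063 genes. The 90 genes higher (red) and 28 lower (blue) across both preparations lie in the upper right and lower left, and the other 10945 genes (grey) spread around 0 with an overall r of 0.25.

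**Figure D3:**
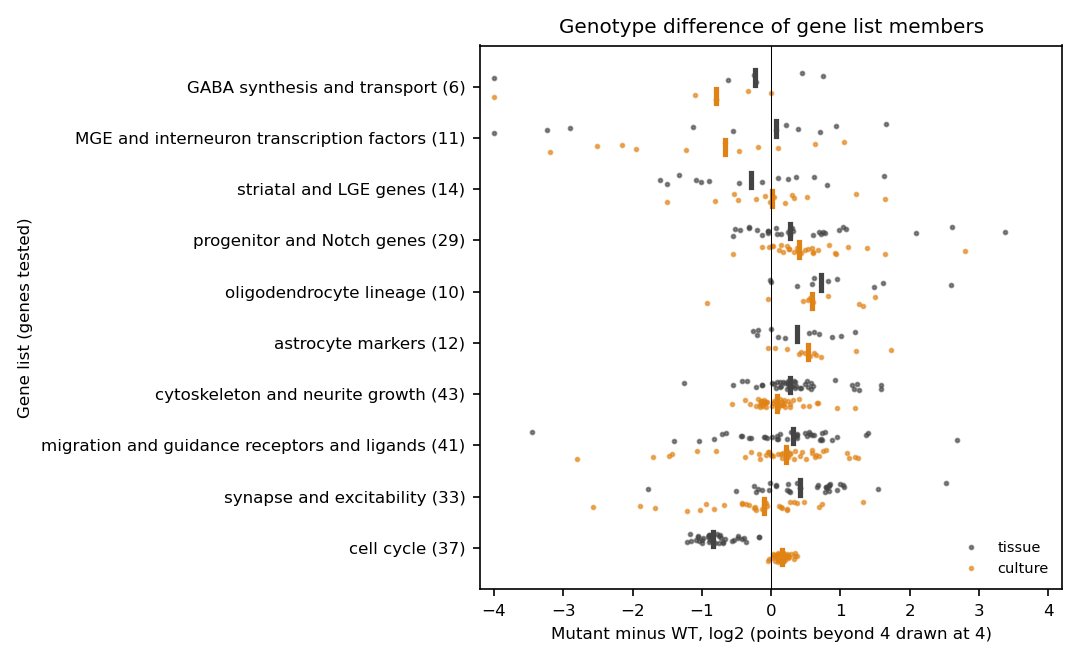
Genotype difference (horizontal axis, log2; points beyond 4 in size drawn at 4) of each tested member of 10 gene lists (vertical axis, number tested in brackets), grey for tissue and orange for culture, with the median as a thick bar. Cell cycle genes lie below 0 in tissue (median −0.84) and around 0.16 in culture.

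The preparations differed far more than the genotypes did. In culture the actin-binding protein gene Tagln was higher than in tissue by 8.87 ± 0.50 and Acta2, smooth muscle actin, by 7.43 ± 0.12 (adjusted p = 1.7e-05 and 3.0e-08). The small heat shock gene Cryab (7.14), the steroid dehydrogenase gene Akr1c14 (6.75), the galectin gene Lgals3 (6.33), the transcription cofactor gene Vgll3 (6.19), Anxa1 (64.2-fold), the epoxide hydrolase gene Ephx1 (5.90), Ecrg4 (5.82), Crhbp (5.64), Bmp6 (5.51) and the peptidase gene Mme (5.25) also rose. In culture the embryonic globin genes fell, Hbb-y by 10.63 ± 0.12 and Hba-x by 6.79 ± 0.22, Hbb-b2 by 5.79, the erythroid haem enzyme gene Alas2 by 5.58, the apelin receptor gene Aplnr by 6.12, the endothelial tight junction gene Cldn5 by 4.89, the pericyte channel gene Abcc9 by 4.83 and Cd34 by 4.51. Igf2 (−5.14), Slc38a5 (−4.80), Apod (−4.67) and Crabp2 (−4.57) fell as well. In this set all but Cldn5 had at least 1 culture array at the floor, so the sizes of those falls depend on where the floor was set. Tagln, Anxa1, Crhbp and Bmp6 in WT tissue, and Cryab, Akr1c14 and Lgals3 on 1 mutant tissue array, were at the floor. Globin probe sets can share sequence between paralogs, so levels of single globin genes are uncertain. Over all genes 2171 were higher and 2126 lower in culture (886 and 573 by at least 2-fold; 5282 at an unadjusted p under 0.05). Without either mutant tissue array 1559 to 1565 were higher and 1301 to 1313 lower, and with mutant arrays alone, a choice made after the data were seen, 2395 and 2417.

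By list, all 6 red blood cell genes (median −5.68, camera adjusted p = 7.8e-07; adjusted p = 0.39 with an estimated correlation) and 5 of 8 endothelial markers (median −1.42, camera adjusted p = 0.0028; adjusted p = 0.43 with an estimated correlation) fell in culture. Of 11 MGE and interneuron transcription factors 10 were lower and 1 higher (median −1.18, camera adjusted p = 0.00013; adjusted p = 0.39 with an estimated correlation). The falls were led by St18 (−4.15 ± 0.21), Lhx8 (−3.93 ± 0.28), Prox1 (−2.39 ± 0.26) and Nkx2-1 (−1.94 ± 0.40), and Maf was the 1 that rose (1.65 ± 0.14). Of 14 striatal genes 7 fell and 1 rose (median −0.79, camera adjusted p = 0.0083; adjusted p = 0.39 with an estimated correlation), among them Isl1 by 2.93. Progenitor and Notch genes split, 9 higher and 13 lower of 29 (camera adjusted p = 0.15), in which Hes5 fell by 4.21 ± 0.33 and the inhibitor gene Id3 rose by 3.08 ± 0.14. Stress and amino acid response genes rose, 11 of 13 with 1 lower (median 1.09, camera adjusted p = 3.3e-05; adjusted p = 0.39 with an estimated correlation), including the metallothionein genes Mt1 (3.46) and Mt2 (3.24) and the asparagine synthetase gene Asns (2.41). Cholesterol synthesis genes rose in 9 of 14 (median 0.48, camera adjusted p = 0.0017; adjusted p = 0.39 with an estimated correlation) and synapse genes in 9 of 33 with 2 lower (median 0.41, camera adjusted p = 0.029; adjusted p = 0.67 with an estimated correlation). In the cytoskeleton list 18 of 43 fell and 7 rose (median −0.19, camera adjusted p = 0.019; adjusted p = 0.67 with an estimated correlation), a call lost with the deposited scaling kept (adjusted p = 0.091). Among interneuron genes Sst (2.20 ± 0.45) and Reln (2.13 ± 0.49) were higher in culture, Htr3a (−1.48 ± 0.20) was lower, and the list did not pass (camera adjusted p = 0.80, with a median of −0.03 opposite in sign to the test). Of the other lists 0 passed, with camera adjusted p between 0.15 and 0.76: 1 of 10 oligodendrocyte genes rose and 5 fell (Olig2 −2.31 ± 0.20), and 5 of 12 astrocyte markers rose and 3 fell (Clu 2.89 ± 0.10). Counts of genes higher and lower were 7 and 3 of 15 for glycolysis and hypoxia, 8 and 11 of 41 for migration, and 1 and 3 of 11 for microglia. They were 2 and 4 of 9 for pericytes and mesenchyme, 2 and 6 of 37 for cell cycle, and 2 and 1 of 7 for immediate early genes. For GABA genes they were 1 and 1 of 6, and for septal, preoptic and diencephalic genes 0 and 2 of 6. They were 0 and 0 of 3 for pallial genes, 1 and 0 of 3 for choroid plexus, 1 and 1 of 4 for sex-linked genes and 0 and 0 of 2 for the targeted genes. Adjusted over the list alone, striatal genes had 8 lower, GABA genes 1 higher and 3 lower, migration 9 higher and 11 lower, pericytes and mesenchyme 3 and 5, cell cycle 0 and 3, sex-linked genes 1 and 2, and the other lists the same counts.

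The log2 ratio of the 3′ to the 5′ Actb control probe set lay between 0.27 and 0.49, and that of Gapdh between −0.52 and −0.33. Hybridisation spikes had mean log2 signals between 10.3 and 10.7. The poly-A spikes, added to the RNA before labelling, were at 12.1 in WT tissue, 11.5 and 11.4 in mutant tissue, 10.97 in WT culture and 10.93 in mutant culture, so they followed genotype within tissue and preparation overall. The 5′ 18S rRNA control probe set read 11086 in WT tissue, 3958 and 728 in mutant tissue, 7772 in WT culture and 1906 in mutant culture, higher in the WT array of each preparation.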

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

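The interaction tests of single genes, the tests of every probe set, the share of genes with the same sign in culture and the test of RNA input were set before the results were seen; the camera tests of the interaction and the other tests weighed here were chosen after, as were the split of that share by direction, the shares over all tissue calls and the use of the share to weigh chance effects of an array.

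The genotype effect differed between culture and tissue by the interaction term for 245 genes with a more positive effect in culture and 251 with a more negative one. The 5 largest positive differences were in the proteoglycan gene Srgn (3.39), the semaphorin gene Sema3f (3.33), the collagen gene Col6a2 (3.07), the protease gene Htra3 (2.915) and the DNA repair gene Palb2 (2.72). Srgn and Htra3 were at the floor in WT culture, and the 2 probe sets of Htra3 above the intensity filter differed in sign in culture (2.73 and −0.93). The 5 largest negative differences were in Aars2, a mitochondrial alanyl-tRNA synthetase gene (−4.28), Npnt (−3.83), Ndufa4l2 (−3.78), Nxph2 (−3.69) and Vps33b (−3.55). These 10 calls were all lost with the floor at the 40th percentile, without the filter on dim genes and without the intensity trend. With probe sets averaged, 7 of them were lost. Apart from Npnt (7.85), the mean log2 signals of these genes lay between 5.08 (Vps33b) and 5.60 (Srgn), not far above the intensity filter. The calls are thus no firm evidence that genotype acts differently on these genes by preparation. Of the lists, the targeted genes (median 2.32), septal, preoptic and diencephalic genes (−1.70), cytoskeleton and neurite growth genes (−0.31), synapse genes (−0.75) and cell cycle genes (0.99) passed for the interaction. Their camera adjusted p-values were 0.013, 0.032, 1.0e-04, 4.6e-08 and 2.4e-33, with an adjusted p = 0.72 with an estimated correlation for each. Dlx1 was at the floor in every mutant array, so its interaction of 2.41 is only the difference between its levels in WT tissue and WT culture. The value of the targeted genes therefore shows no different effect of genotype on Dlx1. Among 1770 probe sets without a gene name here, of 21602 probe sets tested, 10 were higher and 3 lower in mutants across both preparations.

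Cell cycle genes were lower in mutant than in WT tissue (median −0.84) and slightly higher in mutant than in WT culture (0.16, 35 of 37 above 0). The lowest median among 10000 random lists matched on mean expression was −0.2033, which argues against a signal-dependent bias left in the normalized values. Quantile normalization evens out the signal distributions beforehand, so this test could hardly show a bias in the deposited values. With the deposited scaling kept, the list's median in tissue was also −0.84. A lower share of all progenitors in mutant tissue might lower progenitor and Notch genes too, but their median lay 1.118 above that of the cell cycle genes (95% bootstrap interval 0.80 to 1.53). The list thus did not fall with the cell cycle genes, but this cannot decide on the share of progenitors. Its members Gsx1, Id4 and Jag1 rose with genotype across both preparations, so its median may not follow that share. The bootstrap also took genes as independent. An unusual WT tissue array cannot be told apart from a genotype effect, because the WT tissue group holds 1 array: the median of the list's differences was −0.7418 from WT tissue to WT culture and 0.24 from mutant tissue to mutant culture. Fewer dividing cells in mutant tissue may be the biological counterpart, and it stays open with the share of progenitors and the state of that array.

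Xist was lower and Y-linked genes were higher in mutant arrays in 2 of 2 preparations, with Xist at −2.42 in tissue and −1.72 in culture and the median of 3 Y-linked genes at 1.61 and 0.54. A different share of male embryos among those sampled could give this, but the count of preparations with both shifts, 2, restates the pattern and decides nothing. The labels used here do not give the sex of the embryos, so sex share cannot be told apart from genotype in these arrays. A genotype effect on these genes separate from sex share was not tested.

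Tissue genotype effects were often not shared by culture: of the genes that differed at least 2-fold in both mutant tissue arrays 67.98% had the same sign there, 73.6% of those higher (95% binomial interval 67.8 to 78.9) and 56.1% of those lower (46.9 to 65.0), and over all tissue calls 67.3% of the higher and 47.2% of the lower ones did. These intervals take genes as independent, which they are not, so chance effects of the single WT tissue array cannot be told apart from genotype. For a difference in RNA input marked by the poly-A spikes, the median change from mutant tissue replicate 2 to mutant culture was −0.2704 over genes higher in mutant tissue and, sign turned, −0.2404 over genes lower there. Values of 0 or below had been set in advance as evidence against RNA input, but that bound was wrong, because culture differs from tissue in more than RNA input and the genes were chosen with the help of mutant tissue replicate 2, so RNA input cannot be told apart from genotype within tissue, where the spikes were at 12.1 in WT and 11.5 and 11.4 in mutants and the 5′ 18S rRNA control was also higher in WT (11086 against 3958 and 728). A real difference between tissue and culture in the response to genotype may remain, and was tested only by the interaction term.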

How the results depend on the processing

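Most alternatives were fixed before the data were examined. Those that left out genes with equal values in both mutant tissue arrays, left out sex-linked genes or used mutant arrays alone were chosen after seeing the data. Counts are given as higher, then lower, and counts not printed here stayed within 1.5 times the reported one. With 1 WT array per preparation, leaving out a mutant tissue array leaves no residual degree of freedom for the tissue and interaction tests, which were not run that way. No label ties a WT array to a mutant array, so arrays were matched only by preparation, a term of the model across both preparations.

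Without a filter on dim genes, tissue had 11 and 378 genes past the threshold, both preparations together 0 and 0, preparation 963 and 931, and the interaction 393 higher. Few reported calls were among them in tissue (15 of 1691) and for the interaction (2 of 496), and 1658 of 4297 were for preparation. Culture size counts were then 1216 and 1254, Pearson's r between tissue and culture 0.094, Spearman's rho 0.061 and the share of the same sign 53.6%. With a stricter filter the interaction had 441 and 426 genes, culture size counts were 59 and 72, and 4 lists passed for preparation. With the floor at the 40th percentile, tissue had 0 and 0 and the interaction 0 and 0. Genes with equal values in both mutant tissue arrays account for the losses at the higher floor and, in part, without the filter: there were 15 of 11063 in the reported setting, 101 of 11343 at the higher floor and 1623 of 18193 without the filter. Without them, the higher floor gave 1264 and 1030 genes in tissue (1678 shared with the 1691 reported) and 511 and 504 for the interaction. Without filter and without them, tissue had 952 and 725 (1563 shared) and both preparations 53 and 20 (71 of 118 shared). Leaving them out of the reported setting gave 397 and 413 for the interaction.

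With the mean of a gene's probe sets, tissue had 269 and 220 genes, both preparations 24 and 11, and the interaction 0 and 4; without genes of equal values as well, 309 and 235, 24 and 8, and 0 and 5. Without an intensity trend, tissue had 0 and 2, both preparations 1 and 3, and the interaction 0 and 0; without genes of equal values as well, 0 and 0, 1 and 1, and 0 and 0. For these 2 settings the cause was not tested. Testing every probe set gave 1469 higher in tissue and 3444 and 3906 for preparation, over more features. The spread of the model over both preparations left 18 and 12 in tissue; that spread includes differences between tissue and culture. A test of the culture arrays in the model of the 4 groups gave 126 lower. Of the gene lists, 0 passed for genotype with an estimated correlation and 3 with fry, and 0 for preparation with an estimated correlation. The tests with an estimated correlation rest on 2 residual degrees of freedom, so a list could hardly pass them.

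Leaving out either mutant tissue array gave 18 to 18 genes higher and 17 to 18 lower across both preparations, 1301 to 1313 lower for preparation, and a same-sign share of 61.4 to 61.9%. Fewer arrays were fitted in these runs. The direction of Nes in tissue turned to −0.28 and −0.49 there, because another of its probe sets became the brightest, and that of C1qb between preparations to 0.00016 in 1 of 2 runs (−0.26 in the other). Of 42 named genes past the threshold across both preparations, 0 kept their call under every alternative, and 39 lost it only without the trend, without the filter, with averaged probe sets or with an array left out. Under the deposited scaling 112 of the 118 genes were shared, and the median over all genes moved by less than 0.1 in every comparison. Signal over background limits the dim genes: the size of a difference from values at or near the floor is uncertain.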

Other observations

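The tests below are those of the report, and the genes and lists were picked for this part after their values were seen.

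Sst rose by 3.05 ± 0.09 (adjusted p = 2.6e-09) and Npy by 1.40 ± 0.07 (adjusted p = 2.6e-07) in mutant tissue, in 2 of 2 arrays each, by limma. Slc32a1 fell there by 4.72 ± 0.30 (adjusted p = 1.3e-06). In culture Sst differed by 0.55 and Npy by 0.53, and WT culture already held Sst at 12.10 against 8.47 in WT tissue (normalized log2). Htr3a, the serotonin receptor gene of another interneuron class, fell in tissue by 1.04 ± 0.19 (adjusted p = 0.0031) and differed by −0.64 in culture.

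The median level of synapse genes was 6.72 in WT tissue, 6.90 and 7.11 in mutant tissue, 7.75 in WT culture and 7.31 in mutant culture (normalized log2). Progenitor and Notch genes had medians of 8.27, 8.88 and 8.96 in tissue and 8.24 and 8.54 in culture, in the same order of arrays. Gaps between such median levels need not equal the median of the genes' own differences. The latter was 0.42 in tissue and −0.11 in culture for synapse genes. For progenitor and Notch genes it was 0.27 in tissue and 0.40 in culture.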
